A study of Homo sapiens with 8 samples.

How the data were processed

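RNA was measured by stranded poly(A) RNA-seq in 8 libraries, 2 in each of 4 groups, taken from the labels: PC3 EphA2 KO, PC3 control, DU145 EphA2 OE and DU145 control. Per the labels' protocols, RNA was fragmented, copied with dUTP in the second strand and sequenced as paired ends on an Illumina NovaSeq. One table of the whole series was used, with 33221 genes and 16 columns of values, a count and an FPKM for each library; 0 columns of such values were left unmapped. The knockout and overexpression columns carry the words of the design text. The control columns carry names that the labels do not repeat: the name for a negative control was read as the non-targeting lentivirus, and the name for an empty vector as the control plasmid. This is a reading by convention, so an exchange of both controls was run as an alternative. Counts of 17 epidermal genes, given under other observations, group the controls as read, but these genes were picked by that grouping and do not test it. Correlations across genes do not settle the reading either, since their order depended on the measure.

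The authors deposited whole-number counts per gene, not normalized, and FPKM, fragments per kilobase of transcript scaled to library depth. Per the submitters' processing notes the tools were cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6, DESeq2 and edgeR, with the GRCh38 build; their roles, the annotation release and the use of strand in counting are not given in the sources used here. Counts assembled per gene from transcripts can divide reads between overlapping genes, so genes that overlap others in the table, antisense ones included, carry that uncertainty. Of 63556 FPKM values at 0, 63550 had a count of 0. Coordinates are those of the table, on GRCh38. Gene names are those of the table, and 33084 of its 33221 IDs were found in a reference name table, which was used for current symbols in gene lists.

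Total counts were 57571919 to 60951530 per library. Mitochondrial genes took 7.80% to 8.51% of counts and the 10 most abundant genes 7.22% to 7.85%. TMM factors ran from 0.973 to 1.03. A floor of 3 counts corresponds to about 0.05 CPM. Replicates were distinct libraries: chi-square per degree of freedom between the counts of replicates was 42.4 to 93.0. The labels do not say that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The median biological coefficient of variation was 0.257 over all genes tested and 0.129 over genes with a mean CPM above 20.

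Comparisons were fitted in edgeR 4.0.16 (R 4.3.3) with the quasi-likelihood test on counts as deposited, with 4 group means over all 8 libraries, which leaves 4 residual degrees of freedom. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 22727. TMM normalization and Benjamini-Hochberg adjustment below 0.05 were used. SEs were computed as the absolute log2 fold change over the square root of F. The difference of responses was the contrast of knockout minus control and overexpression minus control. With 2 libraries against 2, a permutation test of a single gene cannot reach 0.05, so p-values come from models fitted across all genes. CPM in the text are counts scaled to a common library total.

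Before the data were examined, 28 gene lists were fixed, along with the comparisons and the rule for named genes. Of these lists, 27 had at least 5 tested members. They were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over lists within a comparison, and beside it with an estimated correlation and with fry. With an estimated correlation 0 lists passed in camera (0, 1 and 1 at an unadjusted p under 0.05 in the knockout, the overexpression and the difference), and 0 in the directional test of fry (1, 7 and 6; lowest adjusted p = 0.572, 0.115 and 0.0854). The mixed test of fry, which asks whether members change in either direction and does not compare a list with other genes, passed 3, 14 and 13 lists. The median, the mean and the direction of the test differed in sign for some lists, none of them called: mesenchymal genes and androgen receptor genes in all 3 comparisons, integrins and matrix proteases in the knockout and the difference, and ephrin ligands, cadherins and catenins, and G2/M genes in the knockout. Lists not described elsewhere in the text did not pass camera in either line, though hypoxia and glycolysis genes passed the mixed test of fry in both (adjusted p = 0.0416 and 0.0454): ephrin ligands (4 of 8 higher in the knockout and 4 of 8 in the overexpression; camera adjusted p = 0.968 and 0.779), G1/S and DNA replication genes (25 and 20 of 46; 0.968 and 0.377), hypoxia and glycolysis genes (18 and 16 of 28; 0.631 and 0.678), androgen receptor and luminal prostate genes (3 and 6 of 9; 0.968 and 0.556), neuroendocrine genes (4 and 2 of 6; 0.75 and 0.678), mitochondrially encoded mRNAs (8 and 4 of 13; 0.938 and 0.377) and fibroblast and endothelial markers (3 and 5 of 6; 0.938 and 0.678). The list of leukocyte, red cell and liver markers had 4 tested members and was not tested as a set; PTPRC was at 0.139 CPM or less in each library. HBB, HBA1 and HBA2 were at 1.51, 0.578 and 0.646 CPM in DU145 control replicate 1 and at 0 in the other 7 libraries.

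Named genes were EPHA2 and CDH1; per comparison within a line the 10 called genes with the largest rise and the 10 with the largest fall, with a mean FPKM of at least 1 in the higher group and both libraries of 1 group above both of the other, or the 5 with the smallest p in a direction with under 5 calls; up to 4 members with the smallest p per list described; and genes called in both lines. For lists that were not called, the members named past the threshold adjusted over the list alone were chosen after their values were seen. Some items are not reported here. The 7 genes whose responses differed were named because each passed that test.

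Alternatives were the replicate number as a block, a fit of the 4 libraries of a line, no filter, a filter of 50 counts in 2 libraries, DESeq2 size factors, the DESeq2 1.42.0 Wald test, robust moderation, limma-trend on log2(FPKM + 1) for genes with FPKM of at least 1 in 2 libraries, and each library left out in turn, where the lone library of its group is assumed to vary like the others. Exchanged controls, robust moderation within a line, the control against control comparison and the correlation of fold changes were added after the data were seen.

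The fits were tested on simulated data with 200 changed genes in 3 simulations, with the libraries' own means, sizes and dispersions. For the knockout comparison (21644 genes run), edgeR recovered 32% of 100 genes changed 2-fold and 72% of 100 changed 4-fold, with 9 false calls; DESeq2 recovered 57% and 90%, with 55 false calls. For the overexpression comparison (21656 genes run), edgeR recovered 30% and 71% with 11 false calls and DESeq2 63% and 86% with 75. For the difference of responses (21630 genes run), edgeR recovered 3% and 58% with 6 false calls and DESeq2 25% and 73% with 59. A list of 40 genes shifted by 0.5 had a camera p of 2.49e-19 in the knockout simulation and an unshifted list 0.548. Genes were drawn independently there, so this does not test camera on lists with correlated members. In the knockout data the estimated correlation was 0.329 for the ATF4 list and 0.495 for the ribosomal list.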

Results

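The data were RNA-seq counts and FPKM per gene for 8 libraries of prostate cancer cell lines in 4 groups of 2. Libraries labelled PC3, a line derived from a bone metastasis of prostate cancer, came from cells infected with CRISPR/Cas9 lentivirus against EphA2 (PC3 EphA2 KO) or with a non-targeting lentivirus (PC3 control), 72 h after infection. Libraries labelled DU145, a line derived from a brain metastasis, came from cells transfected with an EphA2 expression plasmid (DU145 EphA2 OE) or a control plasmid (DU145 control), 48 h after transfection. EphA2 is a receptor tyrosine kinase for ephrin-A ligands, and the series names an axis of EphA2 and CDH1 (E-cadherin, the adherens junction cadherin of epithelia) in the migration of castration-resistant cells. Total counts per library ran from 57571919 to 60951530, and 25001 to 25680 genes had a count. The table names the controls in a way the labels do not repeat, and their assignment to the lines is a reading by convention. Counts of 17 epidermal genes, given under other observations, group the controls as read, but these genes were picked by that grouping and do not test it.

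EPHA2 (ENSG00000142627, GRCh38 chromosome 1, 16124337 to 16156069, minus strand) was at 39.7 ± 2.86 FPKM (SD, n = 2) in PC3 EphA2 KO against 55.4 ± 0.371 FPKM (SD, n = 2) in PC3 control. It was at 75.2 ± 8.25 FPKM (SD, n = 2) in DU145 EphA2 OE against 58.9 ± 0.12 FPKM (SD, n = 2) in DU145 control. The libraries stood at 41.7 and 37.7 FPKM (PC3 EphA2 KO), 55.1 and 55.6 (PC3 control), 69.4 and 81.02 (DU145 EphA2 OE) and 58.8 and 58.95 (DU145 control). The direction matched each label, and each knockout library still held 11287 or more EPHA2 counts; an mRNA level does not measure loss of the protein after a frameshift, and EPHA2 overlaps another gene in the table. Both libraries of each altered group lay on the same side of both libraries of its control. Over all genes tested, neither EPHA2 difference passed the threshold in edgeR (log2 fold change -0.46, SE 0.09, adjusted p = 0.415 in the knockout and 0.31, SE 0.09, adjusted p = 0.458 in the overexpression). The rise with the plasmid was modest, from 58.9 to 75.2 FPKM, and DESeq2 did not call it either (adjusted p = 0.224). Knockout and overexpression are therefore used below as labels. Adjusted over the list alone, 1 of 9 tested Eph receptors was lower in the knockout, EPHA2 (adjusted p = 0.0132), while EPHA2 did not pass by this adjustment in the overexpression (adjusted p = 0.0566). As a set the Eph receptors did not pass camera in the knockout (3 of 9 higher, adjusted p = 0.469).

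CDH1 (ENSG00000039068, chromosome 16, 68737292 to 68835537, plus strand) moved opposite to EPHA2 in both lines. It was at 28.4 ± 1.04 FPKM (SD, n = 2) in PC3 EphA2 KO against 21.1 ± 0.45 in PC3 control, and at 14.8 ± 0.662 FPKM in DU145 EphA2 OE against 19.3 ± 0.862 in DU145 control (SD, n = 2 each). The log2 fold changes were 0.45 (SE 0.09) and -0.43 (SE 0.09), and in edgeR their adjusted p over all genes was 0.415 and 0.368. Adjusted over the list of classical cadherins and catenins alone, CDH1 was higher in the knockout (adjusted p = 0.0172) and lower in the overexpression (adjusted p = 0.0197). DESeq2 called EPHA2 in the knockout (adjusted p = 0.015) and CDH1 in both lines (adjusted p = 0.0128 and 0.019), but not EPHA2 in the overexpression (adjusted p = 0.224). In the simulations of these comparisons DESeq2 recovered more changed genes but made 55 and 75 false calls, against 9 and 11 in edgeR. Its adjusted p are therefore to be read with caution.

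**Figure D1:**
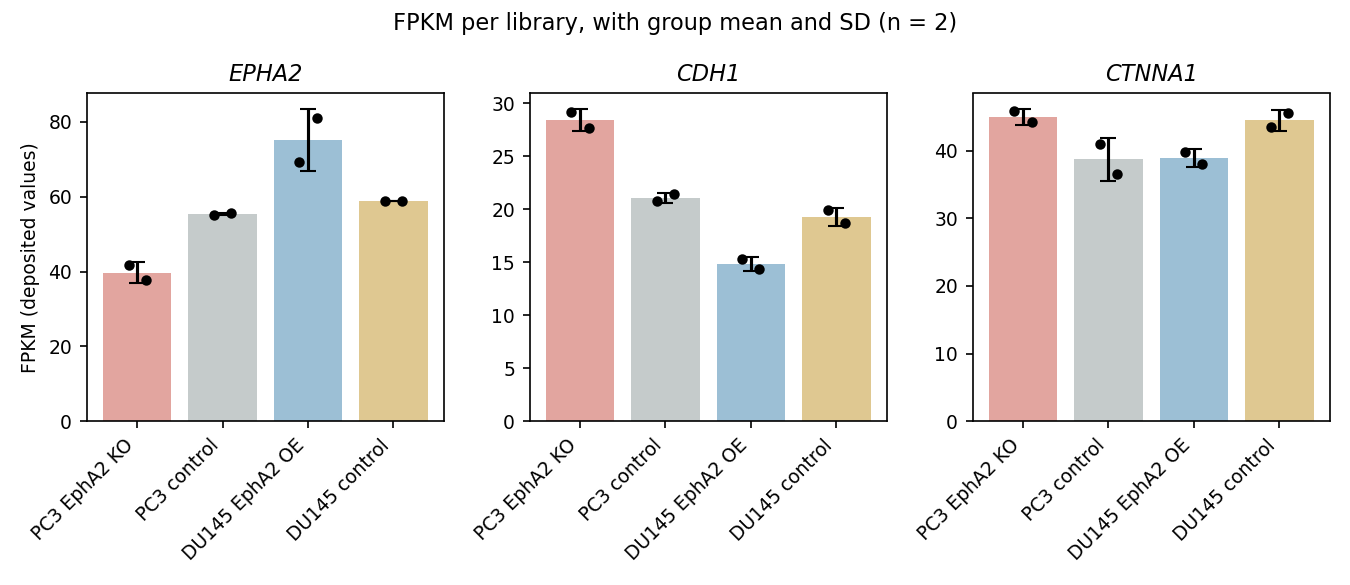
FPKM of EPHA2, CDH1 and CTNNA1 per library (points), with group means (bars from 0) and SD (error bars, n = 2) for the 4 groups. EPHA2 means run from 39.7 in PC3 EphA2 KO to 75.2 in DU145 EphA2 OE, CDH1 runs the other way, and CTNNA1 is read in all 8 libraries.

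The cell line labels have a limit that applies to each comparison. PC3 is known to lack CTNNA1, the alpha-catenin that links cadherins to actin, through a homozygous deletion. CTNNA1 was at 437 ± 43.5 CPM in the 4 libraries labelled PC3 against 435 ± 35.3 CPM in the 4 labelled DU145 (SD, n = 4 each). Correlations of log2(FPKM + 1) across genes ran from 0.9825 to 0.9883 between libraries of 1 group and from 0.9829 to 0.9868 between libraries of different labelled lines; genes are not independent replicates. The control libraries of the lines differed in 13 of 22727 genes in edgeR (8 higher and 5 lower in DU145 control), and in 357 in DESeq2. The edgeR count was 25 without PC3 control replicate 1, 26 without DU145 control replicate 1 and 4 without DU145 control replicate 2. Within the labelled lines edgeR called 6 genes in the knockout and 9 in the overexpression over all 8 libraries, and DESeq2 190 and 309. These counts are no larger than those between the control groups, so they do not by themselves mark a response to EphA2. The groups are called here by their labels. A change in both lines means a change under both labels, which is not shown to be a change in separate cell lines.

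In the libraries labelled PC3, 6 of 22727 genes passed the threshold between EphA2 knockout and control in edgeR, 2 higher and 4 lower. STX6, a SNARE of the trans-Golgi network, rose from 3.87 ± 0.197 to 11.5 ± 0.371 FPKM (SD, n = 2; log2 fold change 1.60, SE 0.10, adjusted p = 0.0132). IKBKGP1, a pseudogene of the NF-kB regulator IKBKG, rose from 0.829 to 9.52 FPKM (log2 fold change 3.52, adjusted p = 0.0365), and its reads cannot be told from those of its parent with certainty. MAPK14, the p38-alpha stress kinase, fell from 13 ± 0.868 to 5.13 ± 0.398 FPKM, and SNX10, a sorting nexin of endosomes, from 13.8 ± 0.455 to 5.34 ± 0.314 FPKM (SD, n = 2 each; log2 fold changes -1.32 and -1.35, adjusted p = 0.0311 and 0.0249). DNAL1, an axonemal dynein light chain, fell from 1.88 to 0.29 FPKM (log2 fold change -2.66, adjusted p = 0.0238), and AC105052 (ENSG00000267645, which overlaps 5 other genes and is uncertain for that reason) from 14.1 to 2.06 FPKM (log2 fold change -2.75, adjusted p = 0.0238).

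Of the next genes by p, SEC22C (log2 fold change 1, adjusted p = 0.052), DDIAS (1.63, adjusted p = 0.0646) and NOVA1 (1.30, adjusted p = 0.0986) lay higher, and MAP3K20, a stress kinase upstream of p38, lay lower (-1.38, adjusted p = 0.0514), none past the threshold. STX6 and AC105052 were called whichever of the 4 libraries was left out. IKBKGP1 and DNAL1 lost the call without PC3 EphA2 KO replicate 1 (adjusted p = 0.0668 and 0.0683) or replicate 2 (0.0643 for both), SNX10 also without PC3 control replicate 2 (0.0785, 0.0823 and 0.0799), and MAPK14 without any of the 4 (0.0764 to 0.105). The count of calls was 13 without PC3 EphA2 KO replicate 1, 21 without PC3 control replicate 1 and 10 without PC3 control replicate 2. With the controls of the lines exchanged, 13 genes passed, AC105052 and SNX10 among them; STX6, IKBKGP1 and DNAL1 lost the call (log2 fold changes 0.12, 0.08 and -0.19) and MAPK14 turned sign without passing (0.23). With the 4 libraries of the line fitted alone, 5 passed, 1 of the 6 among them. DESeq2 called 190 genes (85 higher, 105 lower), all 6 included.

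Genes of the unfolded protein and ATF4 response lay lower in the knockout as a list: 29 of 34 measured members, with a median log2 fold change of -0.26 (camera, adjusted p = 3.24e-06 with the preset correlation and adjusted p = 0.877 with an estimated correlation). HSP90B1, an endoplasmic reticulum chaperone, had a log2 fold change of -0.35, HERPUD1 of -0.61, CHAC1 of -0.80 and SESN2 of -0.88, and 0 members passed in edgeR over all genes or adjusted over the list alone (9 at an unadjusted p under 0.05; 0 called by DESeq2). Cytosolic ribosomal protein genes lay higher, 48 of 53 with a median of 0.16 (adjusted p = 1.21e-05, and adjusted p = 0.877 with an estimated correlation), among them RPLP1 (0.27) and RPL13 (0.32), with 0 members past the threshold in edgeR by either adjustment (7 at an unadjusted p under 0.05; 0 called by DESeq2). Ribosomal protein genes have many processed pseudogenes, and their single values are uncertain. Cholesterol synthesis genes also lay higher, 19 of 25 with a median of 0.17 (adjusted p = 0.00307, and adjusted p = 0.877 with an estimated correlation); HMGCS1, which makes HMG-CoA, was at 1.04 and was the 1 member past the threshold adjusted over the list alone, beside INSIG1 (0.68).

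The remaining lists past the threshold in the knockout were interferon-stimulated genes (26 of 38 higher, median 0.23, adjusted p = 0.00623; IRF1 at 0.52 and SAMD9L at 1.42), nuclear oxidative phosphorylation genes (34 of 44 higher, median 0.12, adjusted p = 0.00848; NDUFS3 at 0.44, UQCRFS1 at 0.24), cytosolic heat shock genes (16 of 18 higher, median 0.15, adjusted p = 0.0199; HSPA6 at 0.97, HSPA8 at 0.84) and YAP and TAZ targets (17 of 24 lower, median -0.14, adjusted p = 0.0481; TGFB2 at -0.86, F3 at -0.52). Each of these 4 had an adjusted p = 0.877 with an estimated correlation. No member of them passed in edgeR, over all genes or adjusted over the list alone; at an unadjusted p under 0.05 lay 5, 4, 0 and 1 members in that order, and DESeq2 called 1 of the interferon-stimulated genes and 0 in the other lists. HSPA8 has many pseudogenes and its value is uncertain. The ATF4 and ribosomal lists were called whichever library was left out, but with the controls of the lines exchanged the ATF4 list turned direction without passing (adjusted p = 0.357) while the ribosomal list passed (1.18e-05). Without PC3 control replicate 2 the other 5 were lost (adjusted p = 0.119 for cholesterol, interferon and heat shock genes, 0.083 for oxidative phosphorylation and 0.331 for YAP and TAZ targets). The heat shock list was also lost without PC3 EphA2 KO replicate 1 (0.0728) or 2 (0.0686) or PC3 control replicate 1 (0.0631), and the YAP and TAZ list without PC3 EphA2 KO replicate 1 (0.0728) or 2 (0.251). With that exchange 3 lists passed, and 2 of the 7 kept call and direction, the ribosomal and the YAP and TAZ list (0.000533). Cholesterol (0.662) and heat shock genes (0.329) turned direction, and interferon-stimulated (0.112) and oxidative phosphorylation genes (0.24) lost the call.

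Lists on adhesion and migration did not pass camera, a test for movement in 1 direction, in the knockout: classical cadherins and catenins (6 of 12 higher, adjusted p = 0.714), epithelial junction and keratin genes (20 of 39 higher, 0.245), mesenchymal genes (11 of 22 higher, 0.968), integrins (12 of 19 higher, 0.968) and matrix proteases and inhibitors (9 of 18 higher, 0.938). In the mixed test of fry, for change of members in either direction, matrix proteases (adjusted p = 0.0055) and integrins (0.0416) passed. Of the epithelial genes 2 were higher adjusted over the list alone, CDH1 among them (adjusted p = 0.028). Adjusted over the list of proteases and inhibitors alone, MMP14, a membrane-bound collagenase, and PLAUR, the urokinase receptor, were higher (log2 fold changes 0.50 and 0.35, adjusted p = 0.00308 and 0.0459) and MMP15 lower (-0.80, adjusted p = 0.0459).

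In the libraries labelled DU145, 9 of 22727 genes passed between EphA2 overexpression and control in edgeR, 5 higher and 4 lower. UHMK1, a kinase that phosphorylates p27, fell from 32.8 ± 0.198 to 8.16 ± 0.466 FPKM and EPDR1, a lysosomal glycoprotein, from 33.0 ± 1.14 to 9.79 ± 0.0898 FPKM (SD, n = 2 each; log2 fold changes -2.06, SE 0.08, and -1.80, SE 0.09; adjusted p = 0.000312 and 0.00112). LASP1, an actin-binding protein of focal adhesions, rose from 16.7 ± 1.55 to 63.3 ± 3.92 FPKM (SD, n = 2; log2 fold change 1.88, SE 0.10, adjusted p = 0.00128). GPD1L fell from 4.98 to 1.25 FPKM and F13A1, the coagulation factor XIII A chain, from 88.5 to 47.5 FPKM (log2 fold changes -2.04 and -0.95, adjusted p = 0.0408 and 0.0449). DNAL1 (2.25), the ST2 receptor IL1RL1 (1.72, uncertain because it overlaps another gene), the steroid and fatty acid enzyme HSD17B12 (1.07) and TNFAIP3, the A20 inhibitor of NF-kB (0.88), rose, with adjusted p of 0.0383, 0.0449, 0.0232 and 0.0449.

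IL17RA lay lower without passing (log2 fold change -1.03, adjusted p = 0.0977). UHMK1, EPDR1 and LASP1 were called whichever of the 4 libraries was left out. DNAL1, HSD17B12, TNFAIP3, GPD1L and F13A1 lost the call without DU145 control replicate 1 (adjusted p = 0.0894, 0.0686, 0.119, 0.0855 and 0.122) or replicate 2 (0.0926, 0.124, 0.175, 0.124 and 0.153). IL1RL1 lost it without either control replicate (0.11 and 0.172) or without DU145 EphA2 OE replicate 2 (0.0575). The overexpression libraries differed more from each other than other replicates did: over 8261 genes with a mean CPM above 20, the median absolute log2 difference was 0.19 between them and 0.0886 to 0.118 in the other groups. The count of calls was 376 without DU145 EphA2 OE replicate 1, 40 without its replicate 2 and 17 without DU145 control replicate 1. With the controls of the lines exchanged, 11 genes passed, UHMK1, EPDR1 and GPD1L among them. There LASP1 (log2 fold change 0.07), HSD17B12 (0.15), TNFAIP3 (0.48) and IL1RL1 (0.68) lost the call, and DNAL1 (-0.22) and F13A1 (0.02) turned sign without passing. With the 4 libraries of the line fitted alone, 0 passed in edgeR (1237 at an unadjusted p under 0.05), and without a filter 4 of the 9. DESeq2 called 309 genes (197 higher, 112 lower), all 9 included.

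**Figure D2:**
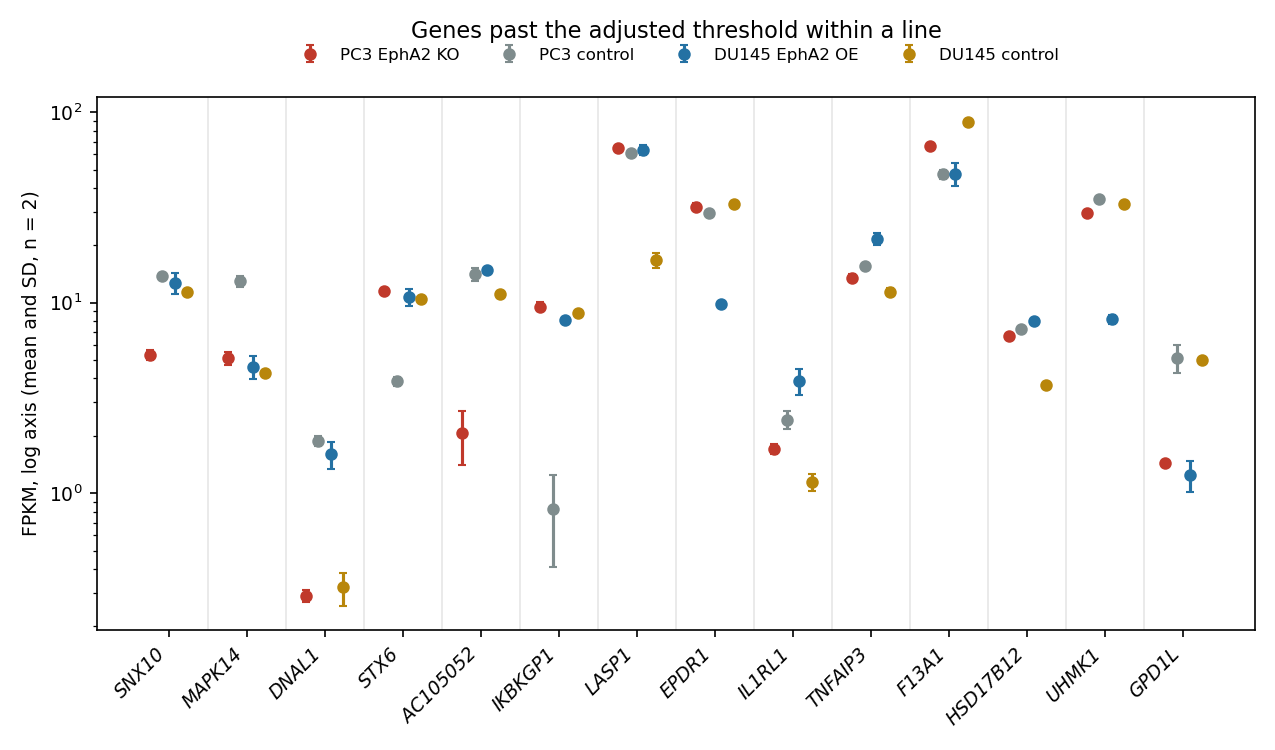
FPKM (log axis; mean and SD, n = 2) in the 4 groups for the 14 genes that passed the threshold within a line. STX6 is lower in PC3 control (3.87) than in the other groups, LASP1 is lower in DU145 control (16.7), and UHMK1 (8.16) and EPDR1 (9.79) are lower in DU145 EphA2 OE.

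Interferon-stimulated genes lay higher with EphA2 overexpression in 37 of 38 measured members, with a median log2 fold change of 0.73 (camera, adjusted p = 3.98e-20, and adjusted p = 0.311 with an estimated correlation). Over all genes 0 members passed in edgeR (19 at an unadjusted p under 0.05; 9 called by DESeq2), and 12 rose adjusted over the list alone, among them IFI6 (2.66), IFI44 (2.07), MX1 (1.52) and OAS2 (3.42), antiviral effectors. OAS2 was at a low level, and a filter on low FPKM or counts dropped it from an alternative fit. NF-kB and inflammatory cytokine genes lay higher in 26 of 28 (median 0.74, adjusted p = 9.54e-15, and adjusted p = 0.311 with an estimated correlation). TNFAIP3 rose over all genes, the only member of any tested list to pass so in edgeR in the overexpression. Adjusted over the NF-kB list alone 7 rose, with CXCL8 (1.02), CXCL2 (1.07) and NFKB2 (0.73). Genes of the unfolded protein and ATF4 response lay higher in 22 of 34 (median 0.43, adjusted p = 5.84e-08, and adjusted p = 0.431 with an estimated correlation), and 15 rose adjusted over the list alone. The amino acid genes ASNS (1.22) and CTH (1.38), the pseudokinase TRIB3 (1.46) and STC2 (0.997) were among them. Under alternatives these fell to as little as 0.143 (ASNS), 0.013 (CTH), 0.564 (TRIB3) and 0.266 (STC2), without a change of sign.

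Both overexpression libraries lay above the control mean in these groups, replicate 2 farther. The median of the interferon list against the DU145 control mean was 0.29 in DU145 EphA2 OE replicate 1 and 1.10 in replicate 2, that of the NF-kB list 0.32 and 1, and that of the ATF4 list 0.21 and 0.70. Without replicate 2 they remained past the threshold (adjusted p = 5.07e-07, 5.04e-05 and 0.00574). With the controls of the lines exchanged the interferon and NF-kB lists passed (adjusted p = 6.5e-28 and 3.43e-06), and the ATF4 list turned direction without passing (0.839).

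Cholesterol synthesis genes lay lower in 21 of 25 (median -0.38, adjusted p = 3.27e-13, and adjusted p = 0.311 with an estimated correlation). LSS (-0.75), HMGCS1 (-0.68) and MVK (-0.81) were among 8 that fell adjusted over the list alone. G2/M genes lay lower in 44 of 46 (median -0.24, adjusted p = 2.29e-10, and adjusted p = 0.457 with an estimated correlation); the mitotic kinesins KIF20A (-0.69) and KIF14 (-0.43) and the spindle gene DLGAP5 (-0.52) fell adjusted over the list alone, and CCNB1 was at -0.52. The per-library medians were -0.21 and -0.64 for cholesterol and -0.08 and -0.44 for G2/M genes in replicates 1 and 2. Without replicate 2 the cholesterol list was called (adjusted p = 2.7e-05) and the G2/M list was not (0.0769). With the controls exchanged the cholesterol list passed (0.000416) and the G2/M list turned direction without passing (0.771).

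Cytosolic heat shock genes lay lower in 17 of 18 (median -0.26, adjusted p = 5.92e-06; HSP90AA1 at -0.52, HSPA4 at -0.21) and replication-dependent histones in 18 of 22 (median -0.35, adjusted p = 0.000529; H2BC12 at -0.53, H2AC6 at -0.61), and both had an adjusted p = 0.431 with an estimated correlation. Immediate early genes lay higher in 21 of 24 (median 0.47, adjusted p = 0.0003, and adjusted p = 0.311 with an estimated correlation; DUSP1 at 0.71, KLF4 at 0.60). No member of these 3 lists passed in edgeR, over all genes or adjusted over the list alone; at an unadjusted p under 0.05 lay 3, 5 and 6 members in that order, and DESeq2 called 0, 0 and 1. Without DU145 EphA2 OE replicate 2 all 3 were lost (adjusted p = 0.104, 0.141 and 0.0769), as they were with the controls exchanged (0.569, 0.484 and 0.35). ERK pathway targets lay higher in 17 of 21 (median 0.32, adjusted p = 0.000368, and adjusted p = 0.311 with an estimated correlation), whichever library was left out; the ERK phosphatases DUSP4 (1.57) and DUSP5 (0.97) and the factor ETV5 (0.53) rose and EMP1 (-2.08) fell, adjusted over the list alone.

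Epithelial junction and keratin genes lay higher in 24 of 39 (median 0.15, adjusted p = 0.0158, and adjusted p = 0.311 with an estimated correlation). Of these, 7 rose and 3 fell adjusted over the list alone. The tight junction claudins CLDN7 (1.46) and CLDN1 (1.10) and the splicing factor ESRP1 (1.73) rose and CDH1 fell. Over all genes 0 members passed in edgeR. Under alternatives the log2 fold change of CLDN7 ran from 0.032 to 1.81, of CLDN1 from 0.695 to 1.424 and of ESRP1 from 0.392 to 2.312. The list was lost without DU145 EphA2 OE replicate 1 (adjusted p = 0.108) or 2 (0.0702) or DU145 control replicate 1 (0.159). Of the listed keratins, KRT5 had 184 to 257 counts and KRT6A 220 to 270 in the 4 libraries labelled DU145, overexpression and control alike, and 0 in each of the 4 labelled PC3. KRT13 had 78 to 190 against 2 to 10 counts, and KRT14 173 to 279 against 0, 12, 0 and 0.

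**Figure D3:**
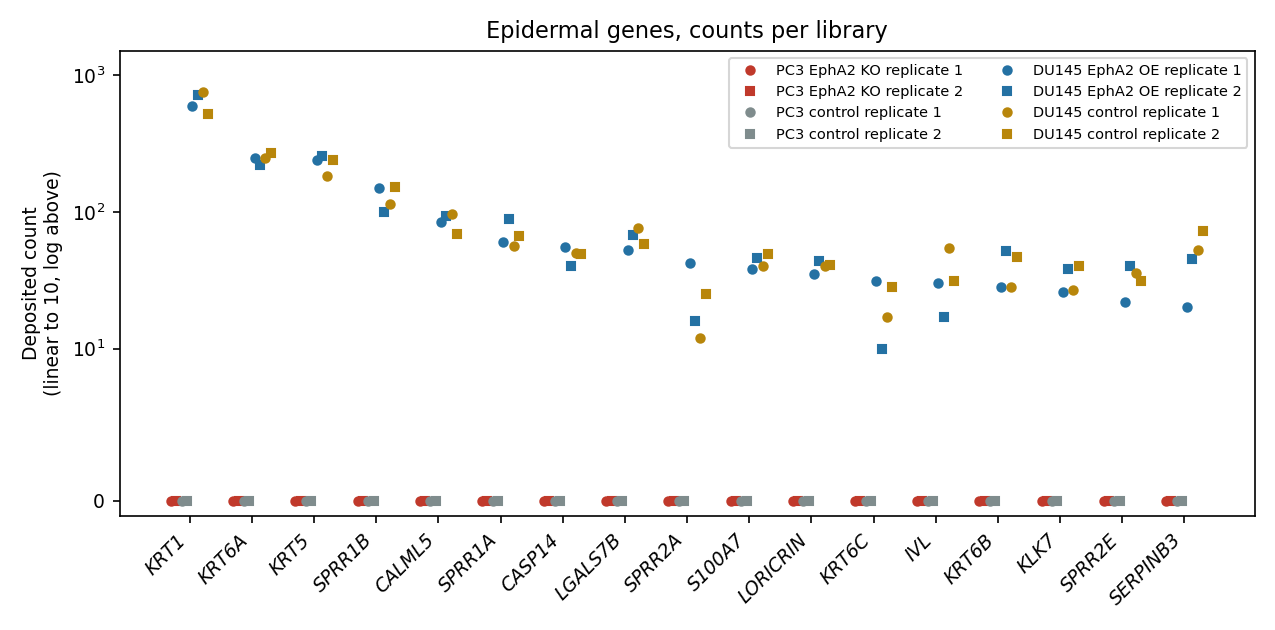
Deposited counts per library (axis linear to 10 and log above; circles, replicate 1; squares, replicate 2) of the 17 genes, of 45 listed for stratified epidermis, with 10 or more counts in each library labelled DU145 and 3 or fewer in each labelled PC3. Each is at 0 in the 4 libraries labelled PC3, and KRT1 is at 520 to 753 in the others.

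Ribosomal protein genes (44 of 53 higher, median 0.10, adjusted p = 0.0204, and adjusted p = 0.74 with an estimated correlation; RPL32 at 0.63, uncertain for its pseudogenes), YAP and TAZ targets (15 of 24 higher, median 0.15, adjusted p = 0.0393, and adjusted p = 0.513 with an estimated correlation) and p53 targets (14 of 25 higher, median 0.05, adjusted p = 0.0494, and adjusted p = 0.311 with an estimated correlation) completed the 13 lists. Adjusted over the list alone, GADD45A (0.99) rose in both of the latter, CCN2 (0.82) among the YAP and TAZ targets and GDF15 (2.35) among the p53 targets. The ribosomal list was lost without DU145 EphA2 OE replicate 1 (adjusted p = 0.181) or DU145 control replicate 1 (0.377, in the opposite direction). The YAP and TAZ list was lost without DU145 EphA2 OE replicate 2 (0.631) or DU145 control replicate 1 (0.159) or 2 (0.103), and the p53 list without the same 3 (0.111, 0.377 and 0.0669). With the controls exchanged the p53 list was lost (0.865) and the ribosomal and the YAP and TAZ list passed (0.0163 and 0.000202); 8 lists passed in all, and 7 of the 13 kept call and direction.

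Other adhesion and migration lists did not pass camera in the overexpression: Eph receptors (3 of 9 higher, adjusted p = 0.377), classical cadherins and catenins (4 of 12 higher, 0.232), mesenchymal genes (13 of 22 higher, 0.678), integrins (8 of 19 higher, 0.678) and matrix proteases and inhibitors (10 of 18 higher, 0.678). Each of them passed the mixed test of fry, for change of members in either direction (adjusted p = 0.00176, 0.00148, 0.00176, 0.00148 and 0.0451 in that order). Adjusted over the list alone, EPHB3 was lower (log2 fold change -1.29, adjusted p = 0.0349), and the junction protein JUP (0.51, adjusted p = 0.0197; list of cadherins and catenins) and the matrix protein TNC (0.48, adjusted p = 0.033) were higher.

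**Figure D4:**
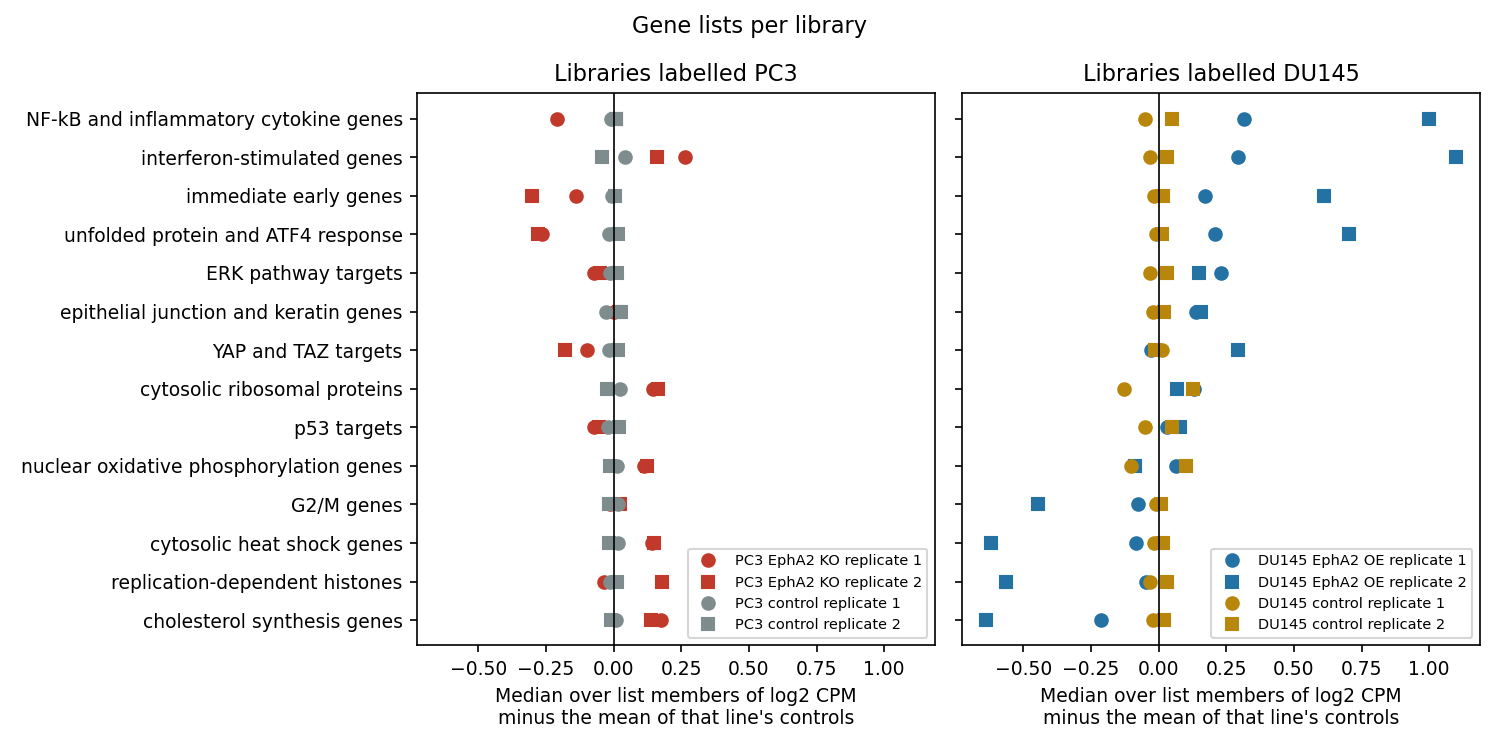
Median over list members of log2 CPM minus the mean of the control libraries of that line, for each library (circles, replicate 1; squares, replicate 2) and each list that passed within a line. In the libraries labelled DU145, the interferon list is at 0.29 and 1.10 and the cholesterol list at -0.21 and -0.64 in the overexpression replicates.

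The last comparison asked whether losing and gaining EphA2 had different effects: the knockout response minus the overexpression response, which share no control library. A gene that follows EphA2 alike in both lines also gives a difference here, as EPHA2 itself would. Loss and gain came with different labelled lines, with lentivirus or plasmid, and at 72 h or 48 h, which cannot be told apart. In edgeR, 7 of 22727 genes passed, 4 with a positive and 3 with a negative difference. UHMK1 (log2 difference 1.83, adjusted p = 0.00434), EPDR1 (1.92, adjusted p = 0.00497), STX6 (1.61, adjusted p = 0.027) and F13A1 (1.46, adjusted p = 0.0335) were positive. DNAL1 (-4.91, adjusted p = 0.00434), LASP1 (-1.75, adjusted p = 0.0163) and AC105052 (-3.12, adjusted p = 0.0352) were negative. DNAL1 was the 1 gene called in both lines, in opposite directions, where independent lists would give 0.00123 in opposite and 0.00114 in the same direction. In DESeq2, 32 genes were called in both lines, 23 in opposite and 9 in the same direction, where independent lists would give 1.41 and 1.33. In each tool both comparisons come from 1 fit that shares the spread estimate of each gene. The lists are therefore not independent, and an excess over these expectations does not show a shared response to EphA2. EPHA2 differed by -0.77 (SE 0.13, adjusted p = 0.169) and CDH1 by 0.88 (SE 0.13, adjusted p = 0.114), and both passed in DESeq2 (adjusted p = 0.000743 and 1.64e-05). In the simulation of this comparison DESeq2 made 59 false calls and edgeR 6.

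UHMK1, DNAL1 and EPDR1 were called whichever of the 8 libraries was left out. LASP1 was lost without PC3 EphA2 KO replicate 2 (adjusted p = 0.0607). STX6 was lost without either PC3 EphA2 KO or PC3 control replicate or without DU145 control replicate 2 (up to 0.0726), AC105052 without any of the 4 control libraries (up to 0.0975), and F13A1 without any library but those of DU145 EphA2 OE (up to 0.104). EPHA2 and CDH1 passed without DU145 EphA2 OE replicate 1 (adjusted p = 0.0225 and 0.0184). The count of calls was 11 to 25 without a library of another group, 323 without DU145 EphA2 OE replicate 1 and 93 without its replicate 2. With the controls exchanged 16 genes passed, 4 of the 7 among them: UHMK1 (1.89) and EPDR1 (1.51) in the same direction and LASP1 (1.86) and STX6 (-1.35) in the opposite one. DNAL1 (0.03) and F13A1 (-0.46) turned sign without passing, and AC105052 (-2.55) lost the call. DESeq2 called 410 genes.

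For lists, 11 of 27 passed as differences, and each had an adjusted p of at least 0.417 with an estimated correlation. Cholesterol synthesis genes (22 of 25 with a positive difference, median 0.51, adjusted p = 4.51e-12; HMGCS1 at 1.73), cytosolic heat shock genes (16 of 18, median 0.49, adjusted p = 2.89e-06), G2/M genes (40 of 46, median 0.27, adjusted p = 4.85e-05) and histones (19 of 22, median 0.49, adjusted p = 0.00425) were higher in the knockout response than in the overexpression response. The ATF4 list (25 of 34 with a negative difference, median -0.91, adjusted p = 9.32e-12), NF-kB genes (27 of 28, median -0.80, adjusted p = 1.49e-09), interferon-stimulated genes (29 of 38, median -0.58, adjusted p = 7.58e-05) and immediate early genes (19 of 24, median -0.66, adjusted p = 0.000241) were lower, as were YAP and TAZ targets, ERK targets and p53 targets (adjusted p = 0.00463, 0.00556 and 0.0411). Adjusted over the list alone, 8 cholesterol genes were positive, and 17 ATF4, 6 NF-kB and 5 interferon genes negative. In lists that did not pass camera, members past the threshold adjusted over the list alone were EPHA2 (adjusted p = 0.00482), CDH1 and CTNNA1 (0.88 and 0.47) against JUP (-0.66) among cadherins and catenins, TNC (-0.69), NDRG1 (-0.54), and 4 positive and 3 negative epithelial genes. Of the proteases MMP14 was positive (0.71, adjusted p = 0.0029) and MMP15 (-1.69) and MMP1 (-6.66) were negative; MMP1 was at 39 FPKM in DU145 EphA2 OE replicate 1 and 1.37 in replicate 2, and its difference was -2.74 without replicate 1. JUP, CTNNA1, TNC, NDRG1, MMP14 and MMP15 turned sign with the controls exchanged. Without DU145 EphA2 OE replicate 2, the lists of G2/M genes (adjusted p = 0.296), interferon-stimulated genes (0.185), YAP and TAZ targets (0.138) and histones (0.0628) were lost. ERK targets were lost without PC3 EphA2 KO replicate 1 (0.0929), and p53 targets without any library but DU145 EphA2 OE replicate 1 (0.0556 to 0.268). With the controls exchanged 5 lists passed, and 2 of the 11 kept call and direction, interferon-stimulated genes (adjusted p = 4.76e-08) and YAP and TAZ targets (3.4e-07). G2/M genes passed in the opposite direction (3.4e-07); ATF4 (0.499), heat shock (0.897), histone (0.793) and p53 genes (0.784) turned direction without passing, and cholesterol (0.118), NF-kB (0.187), ERK (0.0644) and immediate early genes (0.682) lost the call.

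Across 8261 genes with a mean CPM above 20, the fold changes of knockout and overexpression had a Pearson r of -0.184 and a Spearman correlation of -0.197, and 57.7% of genes had opposite signs. These are correlations across genes, which are not independent replicates. With each of the 8 libraries left out in turn the jackknife SD of r was 0.0674, and r was -0.098 without DU145 EphA2 OE replicate 2. With the controls exchanged r was 0.009.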

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

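The tests of cell identity, of the altered EphA2 level and of AC105052 were chosen after the results were seen, and the limit for the altered EphA2 level was changed after its value was known, which turned a negative verdict into an open one; the tests of transcript models and of overlapping genes were fixed before their results.

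The test of the difference sets knockout against overexpression, so a gene that follows EphA2 alike in both lines also differs by it. It does not test the lines alone, since line, delivery and time differ together. Genes whose knockout and overexpression responses differed by it were UHMK1 (log2 difference 1.83), DNAL1 (-4.91), EPDR1 (1.92), LASP1 (-1.75), STX6 (1.61), F13A1 (1.46) and AC105052 (-3.12). Several of them lay at similar levels in 3 groups and apart in the remaining one, with little spread between replicates. A change in the transcript models behind the counts stays open: 0% of the 15 calls within a line shifted by over 10% in counts per FPKM, but of 11989 genes with a mean CPM above 5 only 1 did in each line, so this ratio is nearly fixed and decides nothing. Overlapping genes do not account for the set, since adding their counts kept 82.7% of the median absolute log2 ratio of the 10 calls that overlap another gene, though that of IL1RL1 dropped from 1.77 to 1.11; for AC105052 the sum with its 5 overlapping genes changed by -0.194, and shared reads and a real change cannot be told apart there because the overlapping genes carry most counts. An effect of the altered EphA2 level may account for some of the genes, but the altered group lay farther from the groups of the other line than its control in 7 of the 15 calls and the control did in 8, and with 1 control group per line an effect of EphA2 and a shift in the controls cannot be told apart.

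CTNNA1, which PC3 cells are known to lack, was read in the libraries labelled PC3 at the level of those labelled DU145. The ratio of mean CPM between the labelled lines was 100%, which is consistent with RNA of cells other than PC3 in those 4 libraries. The ratio less its SD was 90.4%, which argues against PC3 cells as the larger part of a mixture with DU145 cells. This holds only if the libraries labelled DU145 hold no PC3 cells, which was not tested. A smaller share of PC3 cells stays open. Which other cells these would be stays open, and for this pattern no biological explanation was tested. Across genes the median r was 0.9846 between libraries of different labelled lines and 0.9852 between groups of the same labelled line. Between the control groups edgeR called 13 genes and DESeq2 357. The same kind of cell under both labels therefore stays open.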

How the results depend on the processing

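The exchange of controls, robust moderation within a line, and all fits of control against control and of the correlation of fold changes were chosen after the data were seen. EPHA2 and CDH1 kept their direction in every alternative run, with log2 fold changes of -0.602 to -0.39 and 0.413 to 0.524 in the knockout and 0.218 to 0.449 and -0.499 to -0.356 in the overexpression. Over the other named genes, 1034 values under alternatives kept direction and side of the threshold, 86 passed newly, 92 no longer passed and 24 changed sign. The cause was not tested where a result moved, beyond what leaving out libraries or genes does by construction. Depth limits genes near 3 counts, about 0.05 CPM. OAS2, GDF15 and EPHB3 in the overexpression and SAMD9L and HSPA6 in the knockout were dropped from an alternative by a filter on low FPKM or counts. Their fold changes therefore rest on low levels. Pseudocount 0.1 and quantile or upper-quartile scaling of FPKM were not run, since the table holds counts.

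With the replicate number as a block, which leaves fewer degrees of freedom, edgeR called 0 genes in the knockout, 3 in the overexpression, 0 in the difference and 0 between the controls, with 1168, 1773 and 1655 genes at an unadjusted p under 0.05 where the count was 0. With this block 6, 11 and 10 lists passed camera. Among those lost were YAP and TAZ targets in the knockout (adjusted p = 0.0535) and p53 targets in the overexpression (0.0658). Deviations of libraries with the same number correlated at -0.00602 (PC3) and -0.00361 (DU145) over all 22727 genes tested, which shows no pairing by number across them. Genes of low count weigh as much as others there, so pairing in a part of the genes stays open. With the 4 libraries of the line alone, the overexpression count was 0 (1237 at an unadjusted p under 0.05) and the knockout count 5, with 1 gene shared. Without a filter the overexpression count was 4, with the stricter filter the difference count was 18, and with robust moderation the knockout and difference counts were 12 and 22. DESeq2 called 190, 309, 410 and 357 genes in the knockout, the overexpression, the difference and between the controls. Its log2 fold changes past the threshold were -0.457 (EPHA2) and 0.453 (CDH1) in the knockout, -0.429 (CDH1) in the overexpression, and -0.76 (EPHA2) and 0.883 (CDH1) in the difference. Leaving out each library gave 6 to 21, 7 to 376, 11 to 323 and 4 to 26 genes, 2 to 6, 6 to 12 and 6 to 13 lists, a correlation of -0.19 to -0.098, and differences of -0.847 to -0.676 for EPHA2 and 0.808 to 0.952 for CDH1. With an estimated correlation 0, 0 and 0 lists passed camera (0, 1 and 1 at an unadjusted p under 0.05), where 7, 13 and 11 passed with the preset one.

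With the controls exchanged, 13 genes passed in the knockout and 16 in the difference, 3, 8 and 5 lists passed, and the correlation was 0.009. Lists that changed direction, with their adjusted p, were ATF4 (0.357), heat shock (0.329) and cholesterol genes (0.662) in the knockout, G2/M (0.771) and ATF4 (0.839) in the overexpression, and p53 (0.784), G2/M (3.4e-07), ATF4 (0.499), heat shock (0.897) and histone genes (0.793) in the difference. The ribosomal list in the overexpression did so without DU145 control replicate 1 (0.377; 2.81e-09 to 0.377 over all left-out libraries). Genes that changed sign, with their log2 fold changes, were MAPK14 (0.227), SESN2 (0.162), CHAC1 (0.443), HMGCS1 (-0.036), HSPA8 (-0.205), PLAUR (-0.074) and MMP15 (0.262) in the knockout. In the overexpression they were DNAL1 (-0.223), F13A1 (0.015), HMGCS1 (0.399), CCNB1 (0.075), EMP1 (0.563) and JUP (-0.261). In the difference they were DNAL1 (0.03), LASP1 (1.855), STX6 (-1.354), F13A1 (-0.457), HMGCS1 (-0.435), MMP14 (-0.208), MMP15 (0.439), JUP (0.883), CTNNA1 (-0.037), TNC (0.188) and NDRG1 (0.503).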

Other observations

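All tests in this part were chosen after the pattern was seen, and the limit of the test for outside RNA was replaced by a comparison with the whole table after its value was known, though the value of 10 met both; the counts of 9 listed genes had been looked at before the list was written.

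Of 45 listed genes of stratified epidermis and squamous mucosa in the table, 17 had 10 or more counts in each of the 4 libraries labelled DU145 and 3 or fewer in each labelled PC3. KRT1, a keratin of the upper epidermis, had 596, 709, 753 and 520 counts in DU145 EphA2 OE replicates 1 and 2 and DU145 control replicates 1 and 2, and 0 in each library labelled PC3. KRT5 had 184 to 257 counts, KRT6A 220 to 270 and the cornified envelope gene SPRR1B 99 to 151 in the libraries labelled DU145, and all were at 0 in the others. Together these 17 genes had 1757 to 1883 counts per library, or 0.00299% to 0.00326% of the total. In the whole table, 15 genes had at least 20 counts in each library labelled DU145 and at most 3 in each labelled PC3, of which 14 are on the list, and 0 genes showed the reverse. In the 17 genes the controls group with the altered groups they were read with, though the genes were picked by that grouping. Correlations across genes did not settle the grouping, since their order depended on the measure. In log2(FPKM + 1) over all genes, those of PC3 EphA2 KO were 0.985 to 0.9855 with PC3 control and 0.9862 to 0.9868 with DU145 control. In log2 CPM over the genes tested, they were 0.9575 to 0.959 with PC3 control and 0.9565 to 0.957 with DU145 control. In both measures DU145 EphA2 OE replicate 1 lay nearer DU145 control and replicate 2 nearer PC3 control. The reading of the controls thus rests on convention. The 17 genes do not test it, since genes that split the libraries with the controls exchanged were not counted.

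Of 36 listed genes that had not been looked at, 10 showed the pattern, where the share of all genes would give 0.0195 (one-sided Fisher's exact test, p = 2.46e-26); 6 listed genes had over 10 counts in every library labelled PC3, among them KRT10 (2215 to 2753) and FLG (1719 to 1993). This is consistent with RNA of human epidermis or squamous mucosa from outside the cultures in the 4 libraries labelled DU145. A response to the EphA2 plasmid is argued against: the median log2 ratio of overexpression to control over the 17 genes was -0.025. Expression by DU145 cells themselves was not tested and stays open: DU145 libraries made elsewhere were not used here, and the design gives cell line, transfection and handling together.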
